A study of Mus musculus with 6 samples.

How the data were processed

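RNA was measured in testes of ICR mice after a scrotal water bath of 25 min at 33 °C (3 libraries) or 43 °C (3 libraries), taken 7 days after the bath. Per the labels, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. Samples were grouped by the temperature in their labels. The design text gives 3 testes per temperature and does not state which mice they came from, so p-values measure the spread between these samples. The labels give no sequencing batch or date.

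The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for mRNA and long non-coding RNA genes and 1 table of back-splice read counts for circRNAs, per the file headers. The FPKM values are normalized to gene length and library size by the authors. Per the submitters' processing notes, FastQC, cutadapt, HISAT2 and StringTie were used and the genome build was mm9; versions, the role of each tool and the use of strand in counting are not given in the sources used here. The coordinates in the tables nevertheless matched GRCm38: 85.8% of 16134 genes matched by symbol to RefSeq's GRCm38.p6 annotation started within 1000 bp of its position. Coordinates are therefore given 1-based, on a build read from the values as GRCm38. Gene coordinates are as deposited, and 1 was added to each deposited circRNA start. The deposited gene table looked filtered before deposit, since the smallest mean FPKM in the group where a gene was higher was 0.500. The deposited counts carried circBase (1047 circRNAs) or CIRCexplorer2 (888) as each circRNA's source, per the file headers, and every circRNA had at least 9 reads in 1 of the groups. Length in nucleotides and number of exons were other deposited annotation columns. Gene symbols and gene classes were those of the tables. In the tables as used here, 1 gene line and 144 circRNA lines were empty and not used.

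Whole-read steps were looked for in genes under 0.5 FPKM in both libraries of a pair: the most frequent log2 ratio, in bins of 0.002, held 0.457% to 0.952% of these genes, too few to recover relative depth. The depth behind the FPKM values is therefore unknown, and only the spread between libraries shows their precision. The circRNA libraries held 14563 to 26988 back-splice reads, and floors for a count of 0 cover counting error only. Summed FPKM was 259043 to 283865 per library. Pairs of libraries were compared for duplicates, and their circRNA counts differed by more than sampling noise in every pair (chi-square per degree of freedom of at least 2.3).

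Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, which removed 931 genes and left 18013. Values were taken as log2(FPKM + 0.1) and fitted with limma 3.58.1 in R 4.3.3 (variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested, and genes were called at an adjusted p under 0.05. Changes are 43 °C minus 33 °C. Protein-coding and non-coding calls are subsets of that fit. "Rose" and "fell" are used for called genes, or for lists by their number of called members and their test. CircRNAs with at least 2 reads in at least 3 libraries were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors from the circRNA counts), and DESeq2 1.42.0 was the alternative. The SE given for a circRNA was derived from edgeR's log2 change and F statistic. The ratio to the host gene was log2 of the circRNA's CPM, with a pseudocount of 0.5 reads in a mean library, minus log2(FPKM + 0.1) of the host gene matched by symbol, tested with limma; 116 circRNAs had no host symbol in the gene table. The numbers of circRNAs detected and of reads were compared with an exact permutation test (two-sided), which cannot go below p = 0.1 with 3 against 3.

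Before the data were examined, 25 gene lists for cell types and pathways of the testis were fixed, and 23 with at least 5 members tested were compared with all other genes by camera with a preset correlation of 0.01. Camera was repeated with a correlation estimated from the data, and its adjusted p is given beside each list; 16 lists passed with the preset value and 0 with the estimated one. The lists of markers overlap in some genes (Piwil1, Hspa2, Cldn5, Cldn11 and others). Genes were named by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 1 FPKM and groups that did not overlap, the 5 largest in each direction among non-coding genes, up to 4 members of each list with the smallest p, and 20 genes fixed by name. Genes outside that rule are said to be chosen after their values were seen.

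The fits were tested on simulated data with 200 changed genes or circRNAs. With each gene's spread set to limma's moderated value, log2 changes of 1 and 2 were recovered for 18% and 84% of changed genes among 18013, with 4 false calls. With the unmoderated spread, recovery was 14% and 56%. The fit with replicate numbers as a block recovered 8% and 78% with the moderated spread and 0% and 0% with the unmoderated one. CircRNA changes of 1 and 2 were recovered for 3% and 26%, with 1 false call, and changes of 3 and 4 for 64% and 74%, with 5, among 1886. The ratio to the host gene recovered 0% at a log2 change of 1 and 1% at 2, with 2 false calls, 66.7% of those called. When changes of 2 and 4 were simulated together it recovered 12% and 63%, with 1 false call, among 1773 circRNAs. Ratio calls as few as the 3 reported could therefore be false. The simulation was first made with the unmoderated spread, ratio changes of 1 and 2 and hosts drawn at random; the moderated spread, the larger ratio changes and the real hosts were taken after those results were seen. A shift of 1 in the Sertoli list was called, with 0 calls among the other 22 lists. The simulated genes varied independently, whereas the estimated correlation in the real data was 0.677 for the Sertoli list and 0.889 for the blood list. The simulation therefore does not show how often lists of correlated genes are called falsely.

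The alternatives tried were other pseudocounts, filters, scalings, a fold threshold, no variance trend, a replicate block, each library left out in turn, an estimated correlation for the list tests, adjustment over non-coding genes alone, other circRNA filters, factors and tools, and a larger ratio pseudocount. Chosen after the data were seen were the removal of 14 seminal vesicle and prostate genes, the summing of back-splice reads per host gene, median-of-ratios factors for circRNAs and matching of hosts by gene ID. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.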

Results

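The series measured RNA in the testes of ICR mice, an outbred laboratory stock, after the scrotum had been held in a water bath for 25 min at 33 °C, the control temperature, or at 43 °C. The testes were taken 7 days later, and 3 libraries per temperature were sequenced. One deposited table held the FPKM of 18944 genes, of which 15029 were protein-coding and 3915 of other classes, called non-coding here. A second table held back-splice read counts of 1935 circRNAs, RNAs in which the end of a downstream exon is joined to the start of an upstream exon. The circRNA libraries held 15615, 22792 and 14707 back-splice reads after the 33 °C bath and 26988, 20149 and 14563 after the 43 °C bath, in the order of replicates 1 to 3. The depth behind the FPKM values is unknown. In a principal component analysis of log2 FPKM, the first component (59.5% of the variance) separated the temperatures, and the second (18.8%) set replicate 3 of the 43 °C bath apart from the other libraries. In that replicate, 14 genes of the seminal vesicle and prostate took 3.47% of all FPKM, against 0.00489% to 0.0156% in the other libraries; these genes were chosen after their values were seen. Pairs of 33 °C libraries correlated at 0.972 to 0.978 across genes (Pearson, log2 scale) and pairs of 43 °C libraries at 0.903 to 0.95. Pairs across the temperatures correlated at 0.850 to 0.918, so the 2 ranges overlapped. Replicate 3 of the 43 °C bath correlated at 0.911 to 0.918 with the 33 °C libraries. Its correlation was 0.926 with replicate 1 and 0.903 with replicate 2 of its own bath.

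Among protein-coding genes that passed, did not overlap between the groups and had a mean of at least 1 FPKM in the higher group, the largest rise was that of Nppb. Nppb, which encodes the B-type natriuretic peptide, was listed at 0 in all 3 libraries of the 33 °C bath and at 7.33, 14.7 and 10.1 FPKM after the 43 °C bath (limma adjusted p = 0.000276; ENSMUSG00000029019.8, chromosome 4:147985788-147987205). Atf3, a stress-induced transcription factor, rose from 0.0341 ± 0.0363 to 9.13 ± 3.36 FPKM (SD, n = 3; limma, log2 change 6.06, SE 0.37, adjusted p = 0.00182). Cldn4, a tight junction protein, rose by a log2 change of 5.26 and Fos, an immediate early transcription factor, by 4.71. Fos was at 4.11 without replicate 2 of the 43 °C bath. The chemokines Ccl2 and Cxcl1 rose by 4.70 and 4.53; Ccl2 stood at 0.572, 17.7 and 3.60 FPKM in the 43 °C libraries, with a log2 change of 5.90 without replicate 1 and 3.54 without replicate 2. In the same family, Ccl7 was listed at 0 in the 33 °C libraries and at 1.32, 9.31 and 2.33 FPKM after the 43 °C bath (log2 change 4.99, and 4.21 without replicate 2). Akr1b7, an aldo-keto reductase, rose by 4.85. Dok5, a docking protein, and Gsta1, a glutathione transferase with close paralogs that could share reads, were listed at 0 in the 33 °C libraries and at 2.28, 4.01 and 1.77 FPKM and 2.19, 4.81 and 1.21 FPKM after the 43 °C bath. The largest falls included Galntl6, from 3.75 ± 0.641 to 0.299 ± 0.326 FPKM (limma, log2 change -3.55, SE 0.51, adjusted p = 0.0107; -4.18 without replicate 2 of the 43 °C bath), and Cyp17a1, an enzyme of androgen synthesis in Leydig cells, from 219.7 ± 72 to 39.6 ± 17.9 FPKM (limma, log2 change -2.55, SE 0.39, adjusted p = 0.0119). Klk1b27, Klk1b21, Klk1b22 and Klk1b24, kallikreins that are close paralogs and could share reads, fell, with log2 changes of -3.55, -3.39, -3.03 and -2.64. Replicate 3 of the 33 °C bath lay apart for these 4 genes, with Klk1b21 at 23.5, 33.8 and 4.76 FPKM in the 33 °C libraries, and without it the log2 changes were -4.445, -4.24, -3.88 and -3.34. Klk1b22 was at -2.43 without replicate 2 of the 33 °C bath and Klk1b21 at -2.64 and -3.98 without replicates 1 and 2 of the 43 °C bath, and these did not pass. Vmn2r68, a receptor gene of another large paralog family, fell, with a log2 change of -2.50, as did Nps, the neuropeptide S gene, at -2.41 and the predicted genes Gm11111 and Gm10750 at -2.54 and -2.39.

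The question of the series was how the RNA of the testis differs after heat exposure, and over all genes 3642 of 18013 tested passed (limma, Benjamini-Hochberg adjusted p under 0.05), 2356 of them higher and 1286 lower after the 43 °C bath. Of these, 1729 rose and 629 fell by at least 2-fold on the log2(FPKM + 0.1) scale, on which all gene changes are given and which understates the change of genes with low values. The groups did not overlap for 7916 genes (43.9%, where chance gives 10%). The number of calls depended on the libraries used. It was 784 without replicate 1 of the 33 °C bath, 163 without its replicate 2 and 354 without its replicate 3. It was 1606 without replicate 2 and 6670 without replicate 3 of the 43 °C bath. The direction of change moved less. Of the 3642 genes called, 3621, 3630 and 3626 kept it without replicates 1, 2 and 3 of the 33 °C bath. Without replicates 1, 2 and 3 of the 43 °C bath, 3604, 3506 and 3583 did. Each such fit shares its libraries with the main one, and genes no longer tested are not counted as kept. Scaled to the Sertoli cell genes, which moved the median log2 change of all genes from 0.05 to -0.59, 314 genes rose and 1182 fell. Of the 20 genes named above that passed, 14 remained called without replicate 1 of the 33 °C bath, 10 without its replicate 2 and 17 without its replicate 3, and 15 without replicate 1 and 15 without replicate 2 of the 43 °C bath.

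**Figure D1:**
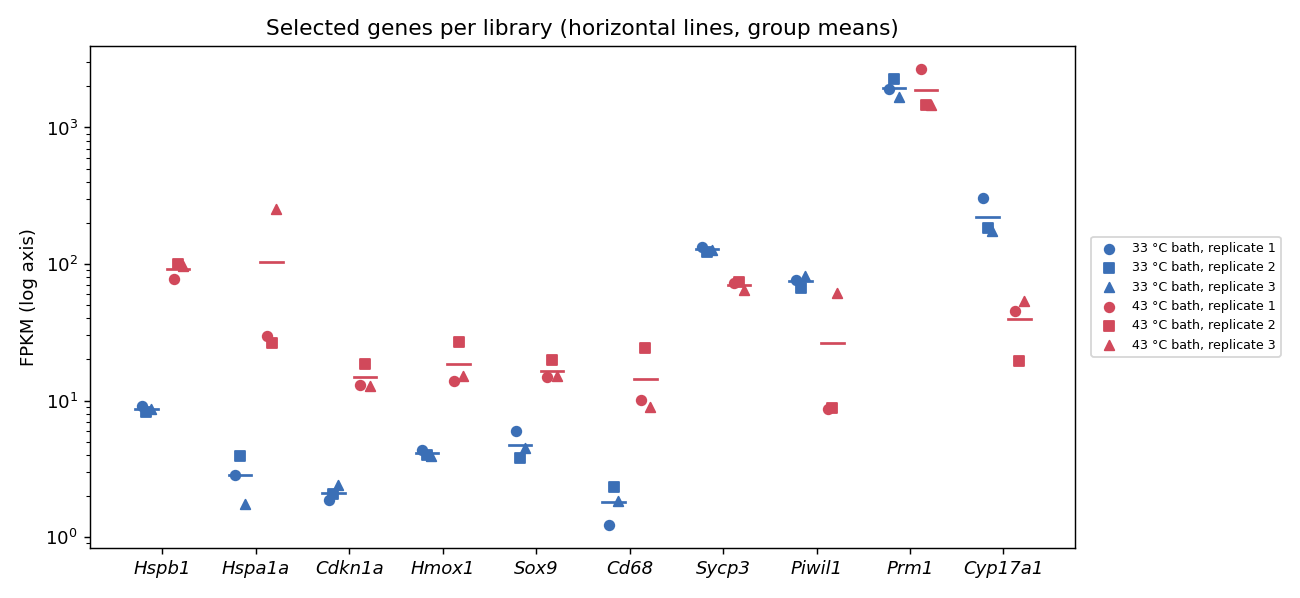
FPKM of 10 genes in each library on a log axis, with the 33 °C bath in blue, the 43 °C bath in red, a marker shape per replicate and a horizontal line at each group mean. Hspb1 lay at 8.22 to 9.10 FPKM in the 33 °C libraries and at 77.7 to 99.7 FPKM in the 43 °C libraries, while for Piwil1 replicate 3 of the 43 °C bath (61.1 FPKM) stood apart from replicates 1 and 2 (8.70 and 8.86 FPKM).

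Of 23 genes tested in the heat shock list, 10 were higher 7 days after the 43 °C bath and 2 were lower. The list also holds heat shock factors and the cold-inducible Cirbp and Rbm3. Rbm3 was among the 10, and the 2 were Cirbp and Hsf5. Hspb1, a small heat shock protein, rose from 8.66 ± 0.441 to 91.3 ± 11.9 FPKM (SD, n = 3; limma, log2 change 3.38, SE 0.15, adjusted p = 0.000276; ENSMUSG00000004951.10, chromosome 5:135887919-135889563). Cryab, another small heat shock protein, rose by a log2 change of 3.97. Hspa1a, an inducible Hsp70 gene, stood at 2.83, 3.91 and 1.74 FPKM in the 33 °C libraries and 29.9, 26.3 and 252 FPKM in the 43 °C libraries, and rose by 4.39, and its near-identical copy Hspa1b rose by 4.12 (3.34 and 3.17 without replicate 3 of the 43 °C bath). The authors' counting could divide reads between these copies. The mitochondrial chaperonins Hspd1 and Hspe1 rose by 1.51 and 1.15, and Hsph1 by 0.85. Of the cold-inducible RNA-binding proteins, Cirbp fell, with a log2 change of -0.63, and Rbm3 rose by 1.20. Hsf5, a heat shock factor of meiotic germ cells, fell, with a log2 change of -1.00, and Hsf1 did not pass, from 2.61 ± 0.278 to 2.48 ± 0.956 FPKM (limma, log2 change -0.13, SE 0.28, adjusted p = 0.770). In the heat shock list, 10 rose and 2 fell of 23 tested (11 and 5 adjusted over the list alone), with a median log2 change of 0.25. The list as a whole did not pass, with camera at adjusted p = 0.10, and adjusted p = 0.442 with an estimated correlation. It passed under quantile normalization (adjusted p = 0.0244) and scaled to the Sertoli genes (adjusted p = 0.0157).

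Genes of apoptosis and antioxidant defence rose as lists. In the apoptosis list, 10 rose and 2 fell of 21 tested (13 and 2 adjusted over the list alone), with a median log2 change of 0.85. For apoptosis genes, camera gave adjusted p = 0.000111, and adjusted p = 0.442 with an estimated correlation. Cdkn1a, a cell cycle inhibitor induced by p53, rose from 2.11 ± 0.259 to 14.8 ± 3.24 FPKM (limma, log2 change 2.74, SE 0.20, adjusted p = 0.00492), Bax by a log2 change of 2.02, Pmaip1 by 2.05 and Casp3 by 1.77, the last 3 being pro-apoptotic. The members that fell were Cyct, the testis form of cytochrome c, and Bcl2l1, an inhibitor of apoptosis, at log2 changes of -1.19 and -0.82. In the antioxidant list, 10 rose and 0 fell of 20 tested (15 and 0 adjusted over the list alone), with a median of 0.84. For antioxidant defence genes, camera gave adjusted p = 1.34e-05, and adjusted p = 0.442 with an estimated correlation. Hmox1, heme oxygenase 1, rose from 4.10 ± 0.234 to 18.5 ± 7.16 FPKM, and Srxn1, Gstp1 and Txn1, enzymes or carriers of thiol redox reactions, rose by log2 changes of 1.68, 2.57 and 1.90. Hsf5, Cyct and Bcl2l1 were named after their values were seen. Of the 20 stress genes named that passed, 15 remained called without replicate 1, 6 without replicate 2 and 10 without replicate 3 of the 33 °C bath, and 18 without replicate 1 and 17 without replicate 2 of the 43 °C bath.

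The lists of meiotic, pachytene, piRNA pathway and sperm tail genes fell, while the lists of spermatogonia and of round and elongating spermatids did not pass. In the list of the meiotic chromosome axis and recombination, 2 rose and 10 fell of 25 tested (2 and 13 adjusted over the list alone). For meiotic axis genes, camera gave adjusted p = 7.40e-05, and adjusted p = 0.442 with an estimated correlation. Sycp3, a component of the axis, fell from 128 ± 5.04 to 70.3 ± 5.00 FPKM (SD, n = 3; limma, log2 change -0.86, SE 0.12, adjusted p = 0.0104), and Spata22, Terb2 and Hormad1, which act in recombination, telomere attachment and synapsis, by log2 changes of -1.13, -1.26 and -0.81. The 2 members that rose were the meiotic cohesins Rec8 (0.52) and Rad21l (1.14), named after their values were seen; scaled to the Sertoli genes, Rec8 was at -0.14. In the pachytene spermatocyte list, 0 rose and 8 fell of 18 tested (0 and 12 adjusted over the list alone), with a median log2 change of -0.77. For pachytene genes, camera gave adjusted p = 1.03e-05, and adjusted p = 0.442 with an estimated correlation. Mybl1, a transcription factor of the pachytene stage, Aurkc, a meiotic kinase, and Tesmin fell, with log2 changes of -0.94, -1.16 and -1.08. In the piRNA pathway list, which protects germ cells from transposons, 0 rose and 10 fell of 17 tested (0 and 16 adjusted over the list alone). For piRNA pathway genes, camera gave adjusted p = 1.58e-07, and adjusted p = 0.442 with an estimated correlation. Piwil2, Ddx4, Mov10l1 and Tdrd12 fell, with log2 changes of -0.97, -0.72, -0.64 and -1.36.

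Piwil1, which is in both the pachytene and the piRNA lists, went from 74.9 ± 7.75 to 26.2 ± 30.2 FPKM and did not pass with all libraries (limma, log2 change -2.14, SE 0.68, adjusted p = 0.0618), but passed without replicate 3 of the 43 °C bath (log2 change -3.07, adjusted p = 0.000656). In that replicate, in which the seminal vesicle and prostate genes given above were high, the pachytene list lay 0.306 below the 33 °C mean on the log2 scale, against 0.886 and 1.20 below in replicates 1 and 2. The piRNA list lay 0.474 below, against 1.12 and 1.22. In the sperm tail list, 1 rose and 4 fell of 23 tested (1 and 4 adjusted over the list alone). For sperm tail genes, camera gave adjusted p = 0.00985, and adjusted p = 0.443 with an estimated correlation. Fsip2 and Spag16 fell, with log2 changes of -0.96 and -0.61, and Catsper4, a channel subunit, rose by 0.49 (-0.16 scaled to the Sertoli genes). The sperm tail call was lost without replicate 2 of the 43 °C bath (adjusted p = 0.0563) and under quantile normalization (adjusted p = 0.151). Among round spermatid and acrosome genes, 0 rose and 2 fell of 18 tested (0 and 1 adjusted over the list alone). For round spermatid genes, camera gave adjusted p = 0.914, and adjusted p = 0.962 with an estimated correlation. The members that fell were Dpy19l2 (-0.86) and Zpbp2 (-0.65). Among elongating spermatid genes, 0 rose and 0 fell of 18 tested (0 and 0 adjusted over the list alone). For elongating spermatid genes, camera gave adjusted p = 0.657, and adjusted p = 0.921 with an estimated correlation. Prm1, a protamine, went from 1944 ± 289 to 1871 ± 711 FPKM (limma, log2 change -0.11, SE 0.26, adjusted p = 0.792), and the elongating list passed without replicate 1 of the 43 °C bath (mean log2 change -0.29, adjusted p = 0.00120). Tnp1, a transition protein (adjusted p = 0.299, and 0.0371 without replicate 1 of the 43 °C bath), and Acrv1, an acrosomal protein (adjusted p = 0.208), had log2 changes of -0.43 and 0.25 with all libraries.

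Spermatogonial genes went both ways. In the list of undifferentiated spermatogonia, 1 rose and 1 fell of 7 tested (1 and 1 adjusted over the list alone). For undifferentiated spermatogonial genes, camera gave adjusted p = 0.817, and adjusted p = 0.921 with an estimated correlation. Cdh1 rose by a log2 change of 1.98 and Id4 fell (-1.31). In the list of differentiating spermatogonia, 2 rose and 0 fell of 11 tested (2 and 0 adjusted over the list alone). For differentiating spermatogonial genes, camera gave adjusted p = 0.817, and adjusted p = 0.921 with an estimated correlation. The members that rose were Ccnd2 (1.67) and Prdm9 (0.81). Zbtb16, a marker of spermatogonial stem cells, and Kit, a receptor of differentiating spermatogonia, had log2 changes of 0.19 (limma adjusted p = 0.588) and 0.01 (adjusted p = 0.984). The median and the camera direction differed in sign for the undifferentiated list (median 0.19, mean 0.03, direction down), and the median and mean differed for the round spermatid list (0.15 and -0.01) and the elongating list (0.05 and -0.03). Of the 22 germ cell genes named that passed, 6 remained called without replicate 1, 1 without replicate 2 and 1 without replicate 3 of the 33 °C bath, and 13 without replicate 1 and 12 without replicate 2 of the 43 °C bath.

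The Sertoli, endothelial, macrophage and blood lists passed as lists, though most members of the Sertoli and macrophage lists did not pass singly, and the Leydig list did not pass. In the Sertoli list, 7 rose and 1 fell of 22 tested (8 and 1 adjusted over the list alone), with a median log2 change of 0.56. For Sertoli genes, camera gave adjusted p = 0.00592, and adjusted p = 0.605 with an estimated correlation. Sox9, a Sertoli transcription factor, rose from 4.75 ± 1.14 to 16.6 ± 2.75 FPKM (SD, n = 3; limma, log2 change 1.79, SE 0.21, adjusted p = 0.00803), and Gdnf, a growth factor for spermatogonial stem cells, and Clu rose by log2 changes of 2.00 and 1.25. The member that fell was Dmrt1, which spermatogonia also express, at -1.07. Amh was below the filter on low values and was not tested. The Sertoli list mean lay 0.853 and 1.02 above the 33 °C mean in replicates 1 and 2 of the 43 °C bath and 0.101 above in replicate 3, the library in which the seminal vesicle and prostate genes were high. Replicate 1 of the 33 °C bath lay 0.270 above that mean, so the groups overlapped for the Sertoli list. In the Leydig list, 1 rose and 2 fell of 15 tested (1 and 2 adjusted over the list alone). For Leydig genes, camera gave adjusted p = 0.713, and adjusted p = 0.921 with an estimated correlation. Cyp17a1 fell as above, Hsd3b1, another steroidogenic enzyme, fell, with a log2 change of -1.41, and Fdx1 rose by 0.92. Star went from 50.8 ± 20.8 to 78.3 ± 28.2 FPKM (limma, log2 change 0.64, SE 0.33, adjusted p = 0.196) and did not pass. Insl3 did not pass either (limma, log2 change 0.70, SE 0.29, adjusted p = 0.121), but passed without replicate 3 of the 43 °C bath (adjusted p = 0.0138).

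In the list of peritubular myoid and smooth muscle cells, 1 rose and 0 fell of 10 tested (3 and 0 adjusted over the list alone), with Des at a log2 change of 1.69. For myoid and muscle genes, camera gave adjusted p = 0.0211, and adjusted p = 0.442 with an estimated correlation. This list mean lay 1.29 above the 33 °C mean in replicate 3 of the 43 °C bath, against 0.385 and 0.494 in replicates 1 and 2, and the call was lost without replicate 3 (adjusted p = 0.104). Acta2, smooth muscle actin, did not pass (log2 change 1.02, SE 0.32, adjusted p = 0.0596, limma) but passed without replicate 1 (adjusted p = 0.0493) or replicate 3 (0.0241) of the 43 °C bath. In the macrophage list, 3 rose and 0 fell of 18 tested (3 and 0 adjusted over the list alone). For macrophage genes, camera gave adjusted p = 0.00744, and adjusted p = 0.443 with an estimated correlation. The macrophage list mean lay 1.20 and 1.21 above the 33 °C mean in replicates 1 and 2 of the 43 °C bath and 0.342 above in replicate 3. Replicate 2 of the 33 °C bath lay 0.449 above that mean, so the groups overlapped for the macrophage list. Cd68, Lyz2 and Tyrobp rose by log2 changes of 2.83, 1.80 and 1.59. In the endothelial list, 7 rose and 0 fell of 9 tested (8 and 0 adjusted over the list alone), with a median of 1.15. For endothelial genes, camera gave adjusted p = 8.37e-05, and adjusted p = 0.442 with an estimated correlation. Among them, Pecam1, Eng and Cdh5 rose by 2.05, 1.47 and 1.34. In the blood list, 4 rose and 0 fell of 5 tested (4 and 0 adjusted over the list alone). For blood genes, camera gave adjusted p = 0.0174, and adjusted p = 0.443 with an estimated correlation. The hemoglobin genes Hba-a1 and Hbb-bs, which have close copies, rose by 2.08 and 1.90; Hbb-bs was at 1.27 and did not pass without replicate 2 of the 43 °C bath. The lymphocyte and epididymis lists had 3 members tested each, too few for a list test, and 0 of them passed over all genes; Rnase10, an epididymal gene, fell when adjusted over the list alone (log2 change -1.07, adjusted p = 0.0578 over all genes and 0.0137 without replicate 3 of the 43 °C bath). Of the 16 somatic genes named that passed, 7 remained called without replicate 1, 2 without replicate 2 and 5 without replicate 3 of the 33 °C bath, and 13 without replicate 1 and 9 without replicate 2 of the 43 °C bath.

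The extracellular matrix, barrier junction and complement and inflammation lists rose. In the matrix list, 8 rose and 0 fell of 18 tested (11 and 0 adjusted over the list alone). For matrix genes, camera gave adjusted p = 0.000114, and adjusted p = 0.443 with an estimated correlation. Timp1, an inhibitor of matrix proteases, rose from 0.893 ± 0.315 to 19 ± 11.1 FPKM (SD, n = 3; limma, log2 change 4.10, SE 0.50, adjusted p = 0.00823; 4.68 without replicate 1 of the 43 °C bath), and Col4a1 and Lamc1, chains of basement membrane collagen and laminin, by log2 changes of 2.17 and 1.66. In the list of blood-testis barrier junctions, 8 rose and 0 fell of 15 tested (9 and 0 adjusted over the list alone), with a median of 1.11. These junctions seal Sertoli cells to each other, but the list is wider. It also holds integrins and Vcl, which are general adhesion genes, and Cldn5, which is in the endothelial list too. For barrier junction genes, camera gave adjusted p = 0.000233, and adjusted p = 0.442 with an estimated correlation. The integrins Itga6 and Itgb1 rose by 1.94 and 1.32, F11r, a junction adhesion molecule, by 1.41 and Vcl by 1.34, as log2 changes. In the complement and inflammation list, 13 rose and 0 fell of 18 tested (14 and 0 adjusted over the list alone), with a median of 1.52. For complement and inflammation genes, camera gave adjusted p = 2.07e-06, and adjusted p = 0.442 with an estimated correlation. C3, the central complement protein, rose by 2.98, the chemokine Ccl12 by 4.25 and the adhesion molecule Icam1 by 2.64. In the ribosomal protein list, 11 rose and 0 fell of 24 tested (15 and 0 adjusted over the list alone), with a median log2 change of 0.41. For ribosomal protein genes, camera gave adjusted p = 2.41e-05, and adjusted p = 0.442 with an estimated correlation. Rps4x, an X-linked gene, and Rplp1 rose by 1.60 and 0.54, Rplp1 being at -0.12 when scaled to the Sertoli genes. Ribosomal protein genes have many pseudogenes that could share reads, and scaled to the Sertoli genes the list did not pass (mean log2 change -0.17, adjusted p = 0.108). In the cholesterol synthesis list, 0 rose and 1 fell of 19 tested (0 and 0 adjusted over the list alone). For cholesterol synthesis genes, camera gave adjusted p = 0.275, and adjusted p = 0.892 with an estimated correlation. The member that fell was Idi1 (-1.29). The list median was 0.02 and its mean -0.10. The list passed without replicate 2 of the 43 °C bath (mean -0.28, adjusted p = 0.0286) and scaled to the Sertoli genes (mean -0.75, adjusted p = 0.0499). Of the 14 genes of these groups named that passed, 10 remained called without replicate 1, 5 without replicate 2 and 6 without replicate 3 of the 33 °C bath, and 11 without replicate 1 and 10 without replicate 2 of the 43 °C bath.

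**Figure D2:**
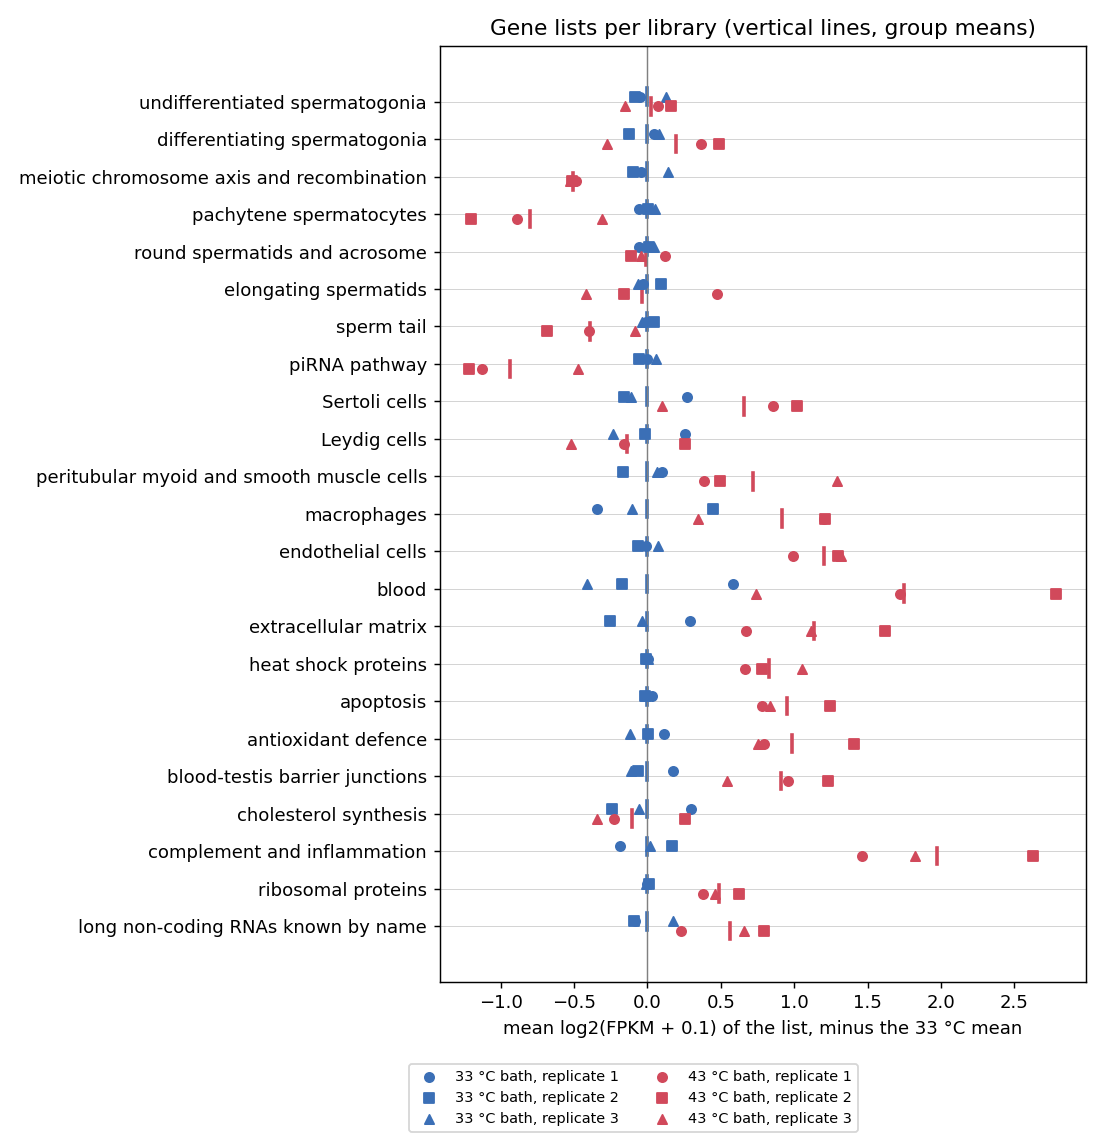
Mean log2(FPKM + 0.1) of 23 gene lists in each library, minus the mean of the 33 °C libraries, with a marker shape per replicate and a vertical line at each group mean. The complement and inflammation list lay 1.46 to 2.62 above the 33 °C mean in the 43 °C libraries, and the piRNA pathway list 0.474 to 1.22 below it.

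More non-coding genes fell than rose, and more protein-coding genes rose than fell. Of 3527 non-coding genes tested, 115 rose and 387 fell, and of 14486 protein-coding genes 2241 rose and 899 fell (limma, adjusted over all genes). Among lincRNAs, which lie between genes, 43 rose and 181 fell of 1390, and among antisense RNAs 16 rose and 86 fell of 854. Gm44969 was listed at 0 in the 33 °C libraries and at 1.66, 3.14 and 0.746 FPKM after the 43 °C bath, and 1700047G07Rik and Gm37350 rose by log2 changes of 3.65 and 2.69. Gm37350 was at 2.05 without replicate 2 and 3.31 without replicate 3 of the 43 °C bath. The antisense genes Gm15726 and Gm20400 rose by 3.70 and 3.07, but use of strand in the counting is not given in the sources used here, so reads of the opposite gene could not be told apart. Gm15726 was at 4.41 without replicate 1 of the 43 °C bath, and Gm20400, at 0.633, 0.436 and 3.38 FPKM in the 43 °C libraries, was not tested without replicate 3. The largest falls were those of 4930405N21Rik, from 22.3 ± 5.17 to 2.51 ± 3.21 FPKM (SD, n = 3; limma, log2 change -3.86, SE 0.78, adjusted p = 0.0191), and of Gm10619, Gm31181, Gm11335 and Gm13821, at log2 changes of -3.49, -3.47, -3.35 and -3.25. In replicate 3 of the 43 °C bath, in which the seminal vesicle and prostate genes were high, 4930405N21Rik, Gm10619, Gm31181 and Gm13821 were higher than in replicates 1 and 2, with Gm10619 at 1.35, 0.495 and 8.94 FPKM. Without replicate 3 their log2 changes were -4.90, -4.58, -4.39 and -4.29, and without replicate 2 they were -3.20, -2.62, -2.86 and -2.54 and did not pass. Gm11335 was at -4.06 without replicate 3 of the 33 °C bath, and at -2.76, not passing, without its replicate 2. In the list of long non-coding RNAs known by name, 5 rose and 0 fell of 16 tested (5 and 0 adjusted over the list alone). For named lncRNA genes, camera gave adjusted p = 0.0275, and adjusted p = 0.498 with an estimated correlation. Neat1, the scaffold of nuclear paraspeckles, rose by 1.92, Dnm3os by 1.85, Peg13 by 0.76, and the small nucleolar RNA hosts Snhg1 and Snhg12 by 0.86 and 1.02, Snhg12 being named after its value was seen. Malat1 had a log2 change of 0.67 (limma adjusted p = 0.118, and 0.0279 without replicate 1 of the 43 °C bath), and the imprinted Meg3 of 0.07 (adjusted p = 0.889).

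The number of non-coding calls was 69 without replicate 1, 12 without replicate 2 and 44 without replicate 3 of the 33 °C bath, and 201 without replicate 2 and 962 without replicate 3 of the 43 °C bath; for protein-coding genes the same 5 values were 715, 151, 310, 1405 and 5708. Scaled to the Sertoli genes, 16 non-coding genes rose and 467 fell and 298 protein-coding genes rose and 715 fell, and under quantile normalization 73 non-coding genes rose and 537 fell. The call of the named lncRNA list was lost without replicate 1 of the 33 °C bath (adjusted p = 0.0687), without replicate 2 (0.0563) or replicate 3 (0.104) of the 43 °C bath, with no filter (0.0717) and scaled to the Sertoli genes (0.0622). Of the 15 non-coding genes named that passed, 4 remained called without replicate 1, 2 without replicate 2 and 4 without replicate 3 of the 33 °C bath, and 7, 5 and 12 without replicates 1, 2 and 3 of the 43 °C bath.

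One circRNA passed. It was a circRNA of 3 exons and 259 nt from the host gene Gm45861 on chromosome 8, at 27552927 to 27558020 on the plus strand, with 0 reads in the 33 °C libraries and 32, 11 and 14 reads after the 43 °C bath (edgeR quasi-likelihood test, adjusted p = 0.00432). It was at least 16.2-fold higher after the 43 °C bath, with a floor of 3 reads for the group at 0. In all, 1 of 1886 circRNAs tested rose and 0 fell with edgeR, 147 had an unadjusted p under 0.05, and DESeq2 called 1, with 96 at an unadjusted p under 0.05. The smallest p among circRNAs that were lower belonged to one from Rint1 on chromosome 5, at 23800595 to 23811034 on the plus strand, with 24, 59 and 22 reads after the 33 °C bath and 4, 3 and 12 after the 43 °C bath. It did not pass (edgeR, log2 change -2.51, SE 0.53, adjusted p = 0.0717), but passed without replicate 3 of the 33 °C bath (adjusted p = 0.0391) or replicate 3 of the 43 °C bath (log2 change -3.61, adjusted p = 0.00310) and in circRNAs with at least 2 reads in all libraries (0.00682). Without replicate 1 of the 43 °C bath 0 circRNAs passed, without replicate 3 of the 33 °C bath 4 did (hosts Gm45861, Rint1, Ascc3 and Casc5), and the Gm45861 circRNA was not tested without replicate 1, 2 or 3 of the 43 °C bath, since fewer than 3 libraries then held reads. The single call without replicate 2 of the 43 °C bath was a circRNA of Scfd2. The groups did not overlap for 304 circRNAs (16.1%), and the biological coefficient of variation was 0.423. Chance gives 10% in a table not filtered by group. Every deposited circRNA had at least 9 reads in 1 of the groups, and such a filter can raise the share without any change. The 16.1% can therefore not be read against 10%. The number of circRNAs detected, above 0 reads, was 1767 ± 42.4 per library after the 33 °C bath and 1798 ± 65.4 after the 43 °C bath (SD, n = 3; exact permutation test, two-sided, p = 0.6, smallest possible p = 0.1). The back-splice reads per library were 17705 ± 4429 and 20567 ± 6223 (exact permutation p = 0.7).

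**Figure D3:**
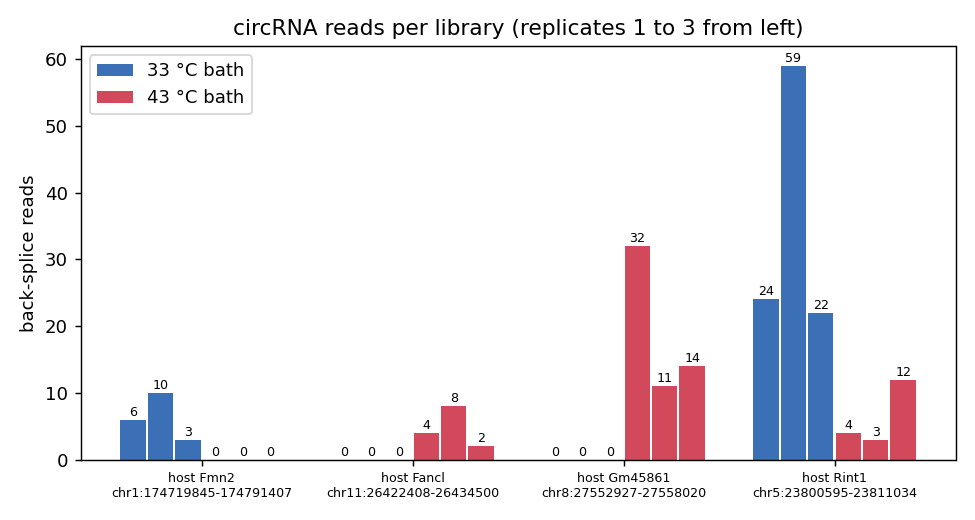
Back-splice reads of 4 circRNAs in each library, with bars from left to right for replicates 1 to 3 of the 33 °C bath (blue) and of the 43 °C bath (red), the count above each bar, and the host gene and position under each group. The Gm45861 and Fancl circRNAs had 0 reads in the 33 °C libraries and the Fmn2 circRNA 0 reads in the 43 °C libraries, while the Rint1 circRNA had 22 to 59 reads after the 33 °C bath and 3 to 12 after the 43 °C bath.

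The changes of circRNAs were compared with those of their host genes. Across 975 host genes, taking the circRNA with the highest mean for each, the log2 changes of circRNA and host correlated at 0.223 (Pearson) and 0.213 (Spearman), where genes are not independent replicates, and no test was made. The 56 circRNAs whose host gene rose had a median log2 change of 0.78, the 343 whose host fell -0.17 and the 1374 whose host was not called 0.03. Of these, 0 circRNAs passed with a host that rose or fell and 1 with a host that was not called. Of 1773 circRNAs tested for their ratio to the host gene, 3 passed and 213 had an unadjusted p under 0.05 (limma). The Gm45861 circRNA was higher relative to its host (adjusted p = 0.0192), whose FPKM was 68.3 and 36.4 at the 2 temperatures. A Fancl circRNA on chromosome 11 at 26422408 to 26434500 went from 0 to 14 reads, while Fancl fell (log2 change -1.11). The circRNA was 3.99-fold higher against a floor of 3 reads, which covers counting error only. Its own change did not pass (edgeR, adjusted p = 0.438), and its ratio to the host passed at adjusted p = 0.0290 (limma). An Fmn2 circRNA on chromosome 1 at 174719845 to 174791407 went from 19 to 0 reads, 7.41-fold lower against the same floor. The change of this circRNA itself did not pass (edgeR, adjusted p = 0.242), and its ratio passed at adjusted p = 0.0219 (limma). The last 2 were named after their values were seen. All 3 were at 0 in 1 group. With 10 times the pseudocount 53 passed, 2 of them among the 3; of the 53, 3 were at 0 in 1 group and 52 had a ratio that changed against the direction of the host gene. In the ratio test, 0 passed in circRNAs above 0 in all 6 libraries or without any 1 of the 6 libraries, where circRNAs with reads in fewer than 3 of the remaining libraries were not tested.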

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

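All alternatives were set before the data were examined except the removal of 14 seminal vesicle and prostate genes, per-host circRNA sums, median-of-ratios factors for circRNAs and host matching by gene ID. Across pseudocounts of 1 and 0.01, both other filters, median-of-ratios and quantile scaling, no variance trend and the gland gene removal, 3123 to 3917 genes were called against 3642. Scaled to the Sertoli genes 1496 genes and 1013 protein-coding genes were called, and with a 2-fold threshold 2358 and 1980, since smaller changes are then left out. Without 1 library, genes called ranged from 163 to 6670, protein-coding genes from 151 to 5708 and non-coding genes from 12 to 962. Adjusted over non-coding genes alone, 298 non-coding genes were called against 502. Without 1 library 14 to 17 lists passed against 16, and with an estimated correlation 0. For circRNAs, 2 passed with the filter above 0 in at least 1 library and 0 of 1032 host sums passed (edgeR, 87 at an unadjusted p under 0.05), and without 1 library 0 to 4. The difference in circRNAs detected was 31, and 7.33 to 68.3 without 1 library. Counting circRNAs at or above the median value it was 127, and 10 (without replicate 1 of the 43 °C bath) to 260 (without its replicate 3) without 1 library. For the ratio to the host gene, 0 passed with reads above 0 in all 6 libraries, 53 with 10 times the pseudocount and 0 without any 1 library, and the host correlation without 1 library was 0.158 to 0.239. Of 109 named genes that passed, 28 to 106 remained called without 1 library, and 107 to 109 were tested and kept their direction. A count test of the genes was not run, since FPKM values are not counts. Unless the construction is named, the cause was not tested.

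Pairing of the samples by replicate number was not seen: the correlations of same-numbered deviations were -0.0859, -0.125 and 0.0319, so not every sample matched its own number best. These correlations were not tested, and with 3 libraries per group they cannot exclude pairing. With a replicate block 2938 genes, 2468 protein-coding and 470 non-coding genes and 17 lists were called, with 2 circRNAs (the Gm45861 and Rint1 circRNAs) and 0 ratios. The list added was that of heat shock genes (adjusted p = 0.0462), and among named genes and circRNAs 5 gained a call (Piwil1, Insl3, Acta2, Fcer1g and the Rint1 circRNA) and 16 lost it (Cirbp, Rec8, Rad21l, Spag16, Catsper4, Zpbp2, Prdm9, Fdx1, Rplp1, Peg13, Snhg1, Snhg12, Tbpl1, Cfap69, Rps16 and Rps14). Of the 3642 genes called without the block, 2632 were called with it.

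Rec8, Catsper4, Rplp1, Rps16 and Rps14 rose with all libraries and were below 0 when scaled to the Sertoli genes, where all genes shifted to -0.59. So were the means of the ribosomal protein list (-0.17) and the named lncRNA list (-0.06), which had passed and did not pass under that scaling. The other named genes and lists that turned direction had not passed. Under that scaling the log2 changes were Rec8 -0.14, Catsper4 -0.16, Acrv1 -0.40, Zbtb16 -0.44, Kit -0.63, Star -0.0129, Rplp1 -0.12, Etv5 -0.15, Sun5 -0.21, Tssk6 -0.16, Cst8 -0.57, Srebf2 -0.20, Rps16 -0.038, Rps14 -0.17 and Meg3 -0.51. Under quantile normalization they were Zbtb16 -0.0232, Kit -0.16 and Meg3 -0.15, and under median-of-ratios scaling Kit -0.0018. List means whose test turned were 0.22 for undifferentiated spermatogonia with no filter, and for round spermatids 0.0728 under quantile normalization and 0.0079 without the gland genes. Without 1 library, the values ranged for Kit from -0.39 to 0.55, for Prm1 -0.40 to 0.0435, for Meg3 -0.0729 to 0.30, for Cst8 -0.21 to 0.27, for Hsf1 -0.41 to 0.0835 and for Cd3d -0.44 to 0.10, and the list means for Leydig cells -0.34 to 0.0484, round spermatids -0.0769 to 0.0396, elongating spermatids -0.29 to 0.16, undifferentiated spermatogonia -0.0404 to 0.12 and differentiating spermatogonia 0.0482 to 0.43. At the observed counts and spread, simulated 2-fold changes were recovered for 3% of circRNAs, and depth and spread were not varied apart.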

Other observations

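The tests of gene families, of the chromosome 14 cluster, of the testis response of seminal vesicle and prostate genes, and of pachytene RNA as a source of the X-linked pattern were chosen after the values were seen, as were the 14 seminal vesicle and prostate genes and the X chromosome as a pattern. Families were taken by the letters at the start of the symbol, and 163 were tested with camera. Those described here were picked from them and did not have the smallest p. Cep genes (1 rose and 8 fell of 39, camera adjusted p = 6.43e-06) and Rps genes (13 rose and 0 fell of 43, 9.72e-05) had smaller values than all of them. Cfap, Rpl and Klk genes (camera adjusted p = 0.000360, 0.00129 and 0.00138) had smaller values than the Ifi, Tnfrsf and Klf genes. Intraflagellar transport genes (Ift), which build cilia and the sperm tail, had 5 members that fell and 0 that rose of 14, with a median log2 change of -0.49 (camera adjusted p = 0.000110), and Ift74 fell from 101 ± 4.18 to 59.1 ± 6.49 FPKM (SD, n = 3; limma, log2 change -0.77, SE 0.13, adjusted p = 0.0139), but did not pass without replicate 1, 2 or 3 of the 33 °C bath (adjusted p = 0.0542, 0.0739 and 0.0678). Interferon-induced Ifi genes had 7 that rose and 0 that fell of 11 (median 1.65, camera adjusted p = 0.00169), among them Ifi35 with a log2 change of 1.73. TNF receptor superfamily genes (Tnfrsf) had 7 that rose and 0 that fell of 10 (median 1.68, camera adjusted p = 0.0153), with Tnfrsf12a at 4.07 (3.36 without replicate 3 of the 33 °C bath). Krüppel-like factor genes (Klf) had 7 that rose and 0 that fell of 16 (median 0.62, camera adjusted p = 0.00476), with Klf6 at 2.61, but scaled to the Sertoli genes their median was -0.01, where all genes shifted to -0.59. Under that scaling 3 Ift genes fell, and 3 Ifi, 3 Tnfrsf and 1 Klf genes rose. With an estimated correlation, the adjusted p was 0.911 for each of these families. On chromosome 14, from 3 to 8 Mb, 70 of 97 genes tested fell and 0 rose (median -1.28); 92 of the 97 carry predicted-gene (Gm) symbols, and as close paralogs that can share reads their changes are uncertain.

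For the number of genes called, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 3642 genes and 1 of the 10 splits, the real one, gave as many, the highest of the others being 1. For protein-coding genes the values were 3140 and 0 (1 split as large), and for non-coding genes 502 and 1 (1 split). For circRNAs, the real split called 1, the highest of the others 4, and 6 of the 10 splits gave as many. For the ratio to the host gene, the real split called 3 and the highest other 1 (1 split).

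The lists of several somatic cell types were higher after the 43 °C bath while the meiotic list was lower, and with an estimated correlation none of these lists passed (adjusted p = 0.442 to 0.605). A lower share of germ cell RNA alone would raise the markers of every somatic type alike. The mean log2 change of the Leydig list was -0.799 from that of the Sertoli list (SE 0.138 over libraries), which argues against it as the whole cause. The differences from the Sertoli list were 0.0646 (SE 0.571) for the myoid, 0.260 (SE 0.355) for the macrophage and 0.545 (SE 0.367) for the endothelial list, which do not separate these from it. A lower share of germ cells together with lower Leydig gene expression, or a response of each cell type to the bath, stays open and may apply, since bulk testis RNA cannot divide them.

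In replicate 3 of the 43 °C bath, 14 genes of the seminal vesicle and prostate lay 29.6 to 432-fold above the highest of the other libraries, with Svs5 at 2795 FPKM, Svs2 at 2345 FPKM and Pate4 at 1202 FPKM, together 3.47% of FPKM for all 14. A response of the testis to the bath is argued against by replicates 1 and 2, where these genes had a median log2 difference of -0.494 from the 33 °C mean and 0 lay above all 33 °C libraries in both; Svs3a did so in replicate 2 alone (0.237 FPKM). RNA of accessory sex glands in that library was tested with 12 gland epithelium genes, whose median ratio to the highest other library was 1.23 (bootstrap interval 0.909 to 1.92). The bound set beforehand, under 1.5, was met, but the interval, chosen after the result was seen, spans it, and 5 of the 12 genes had over 1 FPKM elsewhere, which could hide a small share. Gland RNA, whether carried with the tissue or from another sample, therefore stays a candidate source that this test neither showed nor excluded.

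X-linked genes rose more often than autosomal genes: 171 rose and 6 fell of 752 (22.7% and 0.80%), against 2172 and 1275 of 17149 on autosomes (12.7% and 7.43%), with a median log2 change of 0.47 against 0.03. Their median lay above 100% of 10000 autosomal sets matched on mean expression (highest 0.198), which argues against expression level as the cause, and without replicate 3 of the 43 °C bath the offset from autosomes was 0.712 (0.440 with all libraries), which argues against gland RNA. Scaled to the Sertoli genes, 26 X-linked genes rose and 15 fell, and the X median was -0.16 where all genes were at -0.59. A lower share of RNA from pachytene spermatocytes, in which the X is silenced, is a candidate explanation: replicate 3 had an X offset of 0.0478, against 0.602 and 0.834 in replicates 1 and 2, and its pachytene list lay 0.737 above their mean. That rests on 1 library and was found in the same data, so a higher X output within cells cannot be told apart from it. A higher median was not particular to the X. The Y chromosome had a median log2 change of 0.39, where the highest autosomal median was 0.129 (chromosome 19). Of 83 Y-linked genes tested, 12 rose and 3 fell (14.5% and 3.61%), and the source of the Y values was not tested.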
